A study of Homo sapiens with 110 samples.

How the data were processed

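Total RNA of 110 hepatocellular carcinomas, 1 tumour per patient, was labelled as biotinylated cRNA and hybridised to Illumina HT-12 v4 BeadChips, as the labels state. The deposited values are on a log2 scale, quantile-normalised between arrays by the authors before deposition as far as the values show, and rounded to 2 decimals. The submitters' processing notes name BeadStudio as the export tool, without a version, and do not state the steps of the normalization or the log base. The log base was deduced from the values. They run from 6.2 to 15, and a natural or decimal exponent of 15 would lie above 65535, the largest value a 16-bit scanner can record. The normalization was deduced from the sorted values of the arrays, which differed by at most 0.01 between any 2 arrays. No background subtraction is visible in the values. Values near the array median of 6.76 therefore hold background.

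Probes were given the symbol of the platform table, which held 30121 of the 47231 probes, 30113 with 1 symbol and 8 with several. The Entrez number served to check or update the symbol of 30074 probes. The other 17110 probes had no gene name here and were counted without one. Before any table was made, 166 probes of Y-linked genes or XIST were left out. The remaining 29947 probes stood for 19939 genes, of which 6653 had more than 1 probe. Each gene was read from the probe with the highest mean over all tumours, and no filter on dim probes was applied. List members without a probe in the table were not analysed here.

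The mesenchymal index, 23 gene lists, the gene pairs, the tests, the rule for named genes and most alternatives were fixed before the data were examined. A list score was the mean over its measured genes of their z values across the tumours. Each score was related to the index by Pearson r and Spearman rho, with two-sided p from 100000 permutations, or exact permutation tests under 10 tumours. The Benjamini-Hochberg method adjusted p over the 29 list relations, and an adjusted p under 0.05 for r was the threshold. The smallest p that the permutations can give is 1e-05, which came to 2.9e-05 for r and 3.63e-05 for rho after adjustment. Intervals are 95% intervals from 2000 bootstrap resamples. Every r was computed again without the 2 tumours farthest from the median of the measure on the x axis. A score counted as separate clusters when mclust favoured 2 normal components by BIC, Ashman's D was over 2 and the smaller component held at least 6 tumours. For such scores r is given within each component and not pooled. Random lists, 10000 per list, were matched on size and mean expression.

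Genes outside the index were fitted with limma on the index scaled to SD 1, so that a slope is a log2 difference per SD of the index. All 19921 genes were adjusted together, with 0.5 log2 units per SD as the size limit. Camera compared each list with all other genes, with a preset correlation of 0.01 and with an estimated one. Partial r held the fibroblast matrix, T cell, macrophage and endothelial scores, with Freedman-Lane permutations. Principal components were taken from the 5000 genes with the largest SD. In each list, the 2 members with the largest and the 2 with the most opposite r were named. Outside the lists, the 12 genes with the largest positive and the 12 with the largest negative r were named, among those past the threshold with the same sign in the first and last 55 arrays of the accession order. The 15 genes with the largest SD, the genes of the pairs and the index genes were named too. The labels gave no batch, so the accession order stood in for the position in the series.

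Alternatives covered further normalization, dim genes, the probe of a gene, arrays of low correlation, the parts of the series, the scoring of lists, the genes of the index, the covariates held and the size limit. Leaving out the 5 tumours farthest from the median index, blocks of the accession order and component 1 as a covariate were added after seeing the data, as was the gene fit without the 2 farthest tumours. The methods were tested on simulated data. Slopes of 0.1, 0.2, 0.3 and 0.5 added to 50 genes each were recovered in 57.1%, 82.7%, 92.3% and 99% of cases over 20 draws with a shuffled index. Among the other genes a draw called a median of 8 and at most 679, so that calls came in bursts. A changed set of 12 genes was called in 20 of 20 draws and an unchanged set in 0. Both sets were drawn at random from all genes and tested with the preset correlation. Estimated correlations within the real lists reached 0.639, so the simulation does not give the error rate of camera for them. A relation with no true correlation reached p under 0.05 in 4.4% of 500 data sets, and one with r of 0.3 in 89.6%. The cluster rule called 1% of single normal samples and 99.5% of samples from 2 separate normals. The tests of relations and of clusters drew normal values only. Real scores need not be normal, as BIC favoured 2 components for beta-catenin targets (gain of 105) with Ashman's D of 1.89. How often the rule splits 1 skewed group was not tested. The work used R 4.3.3, limma 3.58.1, mclust 6.1.1 and the package data.table in version 1.17.8.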

Results

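Gene expression was measured in tumours of 110 patients with hepatocellular carcinoma, the most common primary liver cancer, who had been treated first by surgical resection. Each tumour was hybridised to 1 Illumina HT-12 v4 BeadChip, which carried 47231 probes. The labels named 1 group, tumour tissue, and gave no subgroup, outcome, non-tumour liver or batch. The precision of every value below is limited by the number of arrays. Every array had a median of 6.76 on the log2 scale, and values ran from 6.2 to 15. The highest correlation between 2 arrays was 0.967, so no array was a copy of another. The median correlation of an array with the others was 0.665 and 0.717 for the 2 arrays farthest from the rest, at least 0.804 for the others, with a median of 0.901 over all arrays.

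The title of the series asks about mesenchymal subtypes of this cancer, so every comparison followed a mesenchymal index across the 110 tumours. The index was the mean z value of 18 genes known from epithelial-mesenchymal transition, among them the intermediate filament VIM, the transcription factors ZEB1, ZEB2, SNAI1, SNAI2, TWIST1 and TWIST2, and the matrix metalloproteinases MMP2 and MMP14. By the rule used here the tumours formed no separate clusters along the index. BIC favoured 2 components, of 90 and 20 tumours (gain of 25.1), but Ashman's D was 1.68, below the limit of 2. Each index gene was set against the mean of the other index genes. The small calcium-binding protein S100A4 rose by 0.89 ± 0.064 (SE) log2 units per SD of the others (Pearson r = 0.799, Spearman rho = 0.682, r = 0.743 without the 2 farthest tumours, adjusted permutation p = 2.25e-05, n = 110), and the membrane protein EMP3 by 0.71 ± 0.051 (r = 0.799, rho = 0.688, r = 0.736 without 2 tumours, adjusted p = 2.25e-05). VIM rose by 1.06 ± 0.10 (r = 0.705, rho = 0.667, r = 0.669 without 2 tumours), and the receptor kinase AXL by 0.32 ± 0.04 (r = 0.608, rho = 0.507, r = 0.501 without 2 tumours), both at an adjusted p of 2.25e-05. ZEB2 and CDH11 fell into separate clusters and have no pooled r. Of the other 16 genes, 13 passed an adjusted p of 0.05. ZEB1 had a slope of 0.014 ± 0.0097 (r = 0.141, rho = 0.228, r = 0.181 without 2 tumours, adjusted p = 0.14), TWIST1 of 0.031 ± 0.016 (adjusted p = 0.0534) and TWIST2 of 0.033 ± 0.018 (adjusted p = 0.0741). The mean log2 level of ZEB1 was 6.51 and that of SNAI1 6.53, and 6 of the 18 genes had a mean below the 6.76 at the middle of all probes, a level near background.

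Genes of the fibroblast matrix rose with the index, and all 16 measured members passed the test, in the whole set of genes and adjusted over the list alone. COL1A2, a chain of type I collagen, rose by 1.24 ± 0.088 (SE) log2 units per SD of the index (limma, adjusted p = 1.79e-23), and the proteoglycan lumican, LUM, by 1.09 ± 0.079 (adjusted p = 5.94e-23). The members with the smallest r were the platelet-derived growth factor receptor PDGFRB, which rose by 0.45 ± 0.073 (adjusted p = 2.18e-07), and fibrillin, FBN1, which rose by 0.072 ± 0.012 (adjusted p = 5.74e-07). The score of the list had r = 0.818 with the index (95% bootstrap interval 0.732 to 0.875, rho = 0.717, n = 110), and r = 0.782 without the 2 tumours farthest from the median index. Camera gave an adjusted p of 2.93e-39 with a preset correlation and an adjusted p of 2.11e-05 with an estimated correlation. Within the series the relation was 0.839 in the first 55 arrays and 0.817 in the last 55. In 95% of cases random lists of the same size and mean level gave r between -0.479 and 0.374. Of the 13 called list relations that had such a range 3 lay inside it, those of the B and plasma cell score, of the interferon score in its lower component and of the secreted protein score in its lower component, as given below.

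In the list of smooth muscle and pericyte genes 6 of 10 members rose and none fell, with the same counts adjusted over the list alone. The actin-binding proteins TAGLN and CNN1 rose by 0.93 ± 0.10 and 0.14 ± 0.014 (adjusted p = 3.47e-13 and 6.85e-16). DES and LMOD1 had slopes of 0.0048 ± 0.0084 and 0.024 ± 0.013 (adjusted p = 0.739 and 0.184). The score had r = 0.649 with the index (0.479 to 0.767, rho = 0.552, r = 0.541 without 2 tumours), and camera held with an estimated correlation (adjusted p = 0.00354). Of 13 measured targets of TGF-beta and YAP, signalling pathways that drive matrix production and contact-dependent growth, 6 rose and 1 fell, or 6 and 2 adjusted over the list alone. CCN1, a matricellular protein, rose by 0.84 ± 0.063 (adjusted p = 5.51e-22) and LTBP2, a latent TGF-beta binding protein, by 0.40 ± 0.044 (adjusted p = 2.94e-13), while AJUBA fell, with a slope of -0.15 ± 0.042 (adjusted p = 0.00393). The call of AJUBA ended in the last 55 arrays, without the 5 farthest tumours, with blocks of the accession order and with the 4 stromal and leukocyte scores held (adjusted p = 0.25, 0.105, 0.0563 and 0.15). With those 4 scores held TAGLN turned to -0.51 and passed as lower, and LTBP2 turned to -0.13 without passing (adjusted p = 0.00105 and 0.152). AMOTL2 had a slope of -0.11 ± 0.047 (adjusted p = 0.103) and passed in 7 alternatives, with -0.16 without the 5 farthest tumours (adjusted p = 0.0102). This score had r = 0.635 with the index (0.513 to 0.735, rho = 0.549, r = 0.605 without 2 tumours, camera adjusted p = 0.00221 with an estimated correlation). For these lists, and for the T cell, cytotoxic, macrophage, Kupffer cell, endothelial, checkpoint and hepatocyte transcription factor relations below, the permutation p of r was 1e-05, the smallest that the permutations can give, and the adjusted p over 29 list relations was 2.9e-05.

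**Figure D1:**
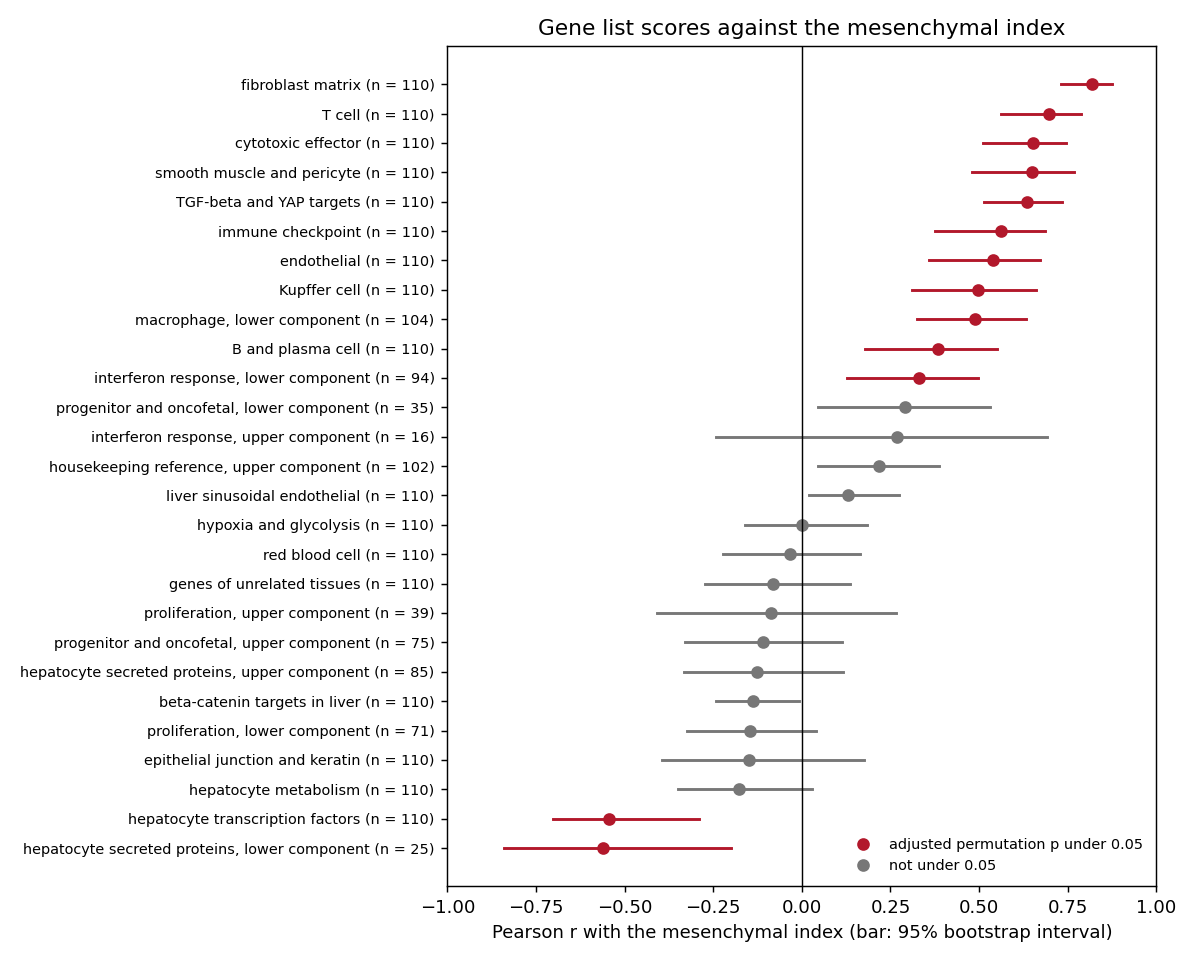
Pearson r of each gene list score with the mesenchymal index, with 95% bootstrap intervals as bars, for all 110 tumours or, where a score fell into separate clusters, within each component of at least 10 tumours; red marks an adjusted permutation p under 0.05. The fibroblast matrix score lies highest at 0.818, and the hepatocyte transcription factor score lies at -0.545.

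Markers of T cells and of cytotoxic lymphocytes rose with the index. In the T cell list 10 of 11 members rose, and the same number did when adjusted over the list alone. The T cell co-receptor CD6 rose by 0.40 ± 0.034 (adjusted p = 2.87e-19) and the interleukin-7 receptor IL7R by 0.56 ± 0.048 (adjusted p = 1.26e-18). The kinase LCK rose by 0.071 ± 0.016 (adjusted p = 0.000205), and TRAT1 had a slope of 0.003 ± 0.015 (adjusted p = 0.913). The slope of TRAT1 was 0.028 with the mean of its probes (adjusted p = 0.00907). The slope of LCK was 0.018 in the last 55 arrays and 0.023 without the 5 farthest tumours, and its call ended in both (adjusted p = 0.598 and 0.234). The T cell score had r = 0.697 (0.563 to 0.787, rho = 0.541, r = 0.694 without 2 tumours), with r = 0.716 in the first 55 arrays and 0.67 in the last 55. All 9 cytotoxic effector genes rose, also adjusted over the list alone. The granzymes GZMK and GZMA rose by 0.49 ± 0.042 and 0.50 ± 0.048 (adjusted p = 1.3e-18 and 9.07e-16), and KLRD1 and GNLY by 0.07 ± 0.014 and 0.15 ± 0.03 (adjusted p = 2.88e-05 and 4.66e-05). Their score had r = 0.653 (0.512 to 0.745, rho = 0.543, r = 0.628 without 2 tumours). With an estimated correlation camera gave adjusted p = 0.00217 for T cells and 0.00368 for cytotoxic genes.

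Of 8 measured immune checkpoint genes 5 rose and none fell, the same count adjusted over the list alone. HAVCR2, an inhibitory receptor of T cells and macrophages, rose by 0.58 ± 0.065 (adjusted p = 6.21e-13) and IDO1, an enzyme that degrades tryptophan, by 0.17 ± 0.026 (adjusted p = 1.19e-07). CD274, which encodes PD-L1, had a slope of 0.0032 ± 0.0076 (adjusted p = 0.816) at a mean level of 6.52, near background, and TIGIT a slope of -0.026 ± 0.013 (adjusted p = 0.151). The score had r = 0.561 (0.375 to 0.686, rho = 0.367, r = 0.533 without 2 tumours, camera adjusted p = 0.0171 with an estimated correlation). In the B and plasma cell list 6 of 9 members rose, also adjusted over the list alone, led by TNFRSF17 at 0.10 ± 0.017 and CD79A at 0.34 ± 0.061 (adjusted p = 1.18e-06 and 2.39e-06). With the 4 stromal and leukocyte scores held TNFRSF17 had 0.054 and CD79A turned to -0.014, and both calls ended (adjusted p = 0.213 and 0.933). FCRL5 and DERL3 had slopes of -0.025 ± 0.022 and -0.013 ± 0.019 (adjusted p = 0.475 and 0.666). Its score had r = 0.385 (permutation p = 0.00016, adjusted p = 0.000422, rho = 0.281, r = 0.418 without 2 tumours, random lists -0.353 to 0.421). The camera call of 0.00103 was lost with an estimated correlation (adjusted p = 0.158). Of 10 interferon response genes 6 rose, or 7 adjusted over the list alone, with IFI44L at 0.26 ± 0.048 and OAS2 at 0.44 ± 0.086 (adjusted p = 4.8e-06 and 2.47e-05). The call of OAS2 ended with the index of transcription factors (0.21, adjusted p = 0.124). With the 4 stromal and leukocyte scores held IFI44L had 0.054 (adjusted p = 0.742) and OAS2 turned to -0.40. ISG15 and IFIT1 had slopes of 0.084 ± 0.10 and -0.012 ± 0.11 (adjusted p = 0.611 and 0.956). The camera call of this list was also lost with an estimated correlation (adjusted p = 0.241). The interferon score fell into separate clusters, with r = 0.33 in the lower 94 tumours (permutation p = 0.00111, adjusted p = 0.00268, rho = 0.293, r = 0.258 without 2 tumours, random lists -0.434 to 0.434) and r = 0.268 in the upper 16 (permutation p = 0.312, adjusted p = 0.394, rho = 0.409, r = 0.238 without 2). The call of the lower component ended without the 5 farthest tumours, in the first 55 arrays, with the index of transcription factors and with the index without leukocyte-expressed genes (r = 0.21, 0.294, 0.105 and 0.207).

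Macrophage markers rose in 8 of 12 cases and fell in none, with the same counts adjusted over the list alone. TYROBP, a signalling adaptor of myeloid cells, rose by 0.83 ± 0.069 (adjusted p = 2.81e-19) and the scavenger receptor CD163 by 0.63 ± 0.055 (adjusted p = 5.09e-18). LAIR1 and FCGR3A had slopes of -0.036 ± 0.02 and -0.10 ± 0.068 (adjusted p = 0.2 and 0.352). LAIR1 passed as lower with the index of transcription factors and FCGR3A without the 5 farthest tumours (adjusted p = 0.0267 and 0.0321). The probe of LAIR1 had a mean of 14.75 and an SD of 0.21, close to the highest value of 15, so that it cannot show a rise of this marker. The macrophage score fell into separate clusters. It had r = 0.489 in the lower component, which held all but 6 tumours (0.325 to 0.633, rho = 0.484, r = 0.415 without 2), and r = 0.955 in the upper 6 (exact permutation p = 0.00694, adjusted p = 0.0144, rho = 0.943, r = 0.935 over the 4 left without 2). The call in these 6 tumours ended with genes above the median mean, with scores by median z and with the index of transcription factors (r = 0.811, 0.724 and 0.919, adjusted p = 0.0903, 0.212 and 0.0834). All 6 lay in the first 55 arrays. This relation was run in 10 alternatives, against 15 for the lower component. It could not be run in the last 55 arrays or without the 5 farthest tumours. Of 6 Kupffer cell markers, which mark the resident macrophages of the liver, 4 rose, also adjusted over the list alone. VSIG4 and FOLR2 rose by 0.20 ± 0.024 and 0.25 ± 0.036 (adjusted p = 4.54e-12 and 1.09e-08), and CLEC4F and CD5L had slopes of -0.015 ± 0.017 and 0.018 ± 0.02 (adjusted p = 0.594 and 0.589). Their score had r = 0.498 (0.31 to 0.662, rho = 0.487, r = 0.437 without 2 tumours). Both lists held in camera with an estimated correlation (adjusted p = 0.00217 and 0.0361). Endothelial markers rose in 9 of 11 cases, also adjusted over the list alone, with PECAM1 at 0.47 ± 0.042 and the TGF-beta co-receptor ENG at 0.45 ± 0.048 (adjusted p = 9.22e-18 and 7.72e-14). KDR and ROBO4 had slopes of -0.0029 ± 0.011 and 0.0061 ± 0.019 (adjusted p = 0.892 and 0.865). The endothelial score had r = 0.538 (0.36 to 0.673, rho = 0.501, r = 0.447 without 2 tumours, camera adjusted p = 0.022 with an estimated correlation). None of the 9 markers of liver sinusoidal endothelium passed limma in either adjustment, with 2 at an unadjusted p under 0.05. Of these 9 markers 5 had a mean below 6.76, near background, against 2 of the 11 endothelial markers, so their lack of a call says little. FCN3 had a slope of 0.33 ± 0.15, LYVE1 of 0.052 ± 0.026, OIT3 of -0.00073 ± 0.022 and CLEC1B of 0.037 ± 0.046 (adjusted p = 0.11, 0.152, 0.987 and 0.62). FCN3 passed at 0.45 without the 2 farthest tumours, 0.50 without the 5 farthest, 0.42 with genes above the median mean and 0.41 with scores by first component (adjusted p = 0.0258, 0.0135, 0.0196 and 0.0366). FCN3 turned to -0.86 and passed as lower with the 4 stromal and leukocyte scores held (adjusted p = 0.0109). LYVE1 passed as higher with the index of transcription factors and with the mean of its probes (adjusted p = 0.0196 and 0.0379). The sinusoidal score had r = 0.131 (permutation p = 0.167, adjusted p = 0.242) and rho = 0.238 (adjusted p = 0.0245), with r = 0.184 without 2 tumours and a camera adjusted p of 0.234, which was 0.0125, in the direction of higher, without the 5 farthest tumours. In the first and last 55 arrays r was 0.745 and 0.548 for smooth muscle, 0.657 and 0.639 for TGF-beta and YAP targets, 0.669 and 0.586 for cytotoxic genes, 0.567 and 0.519 for checkpoints and 0.368 and 0.445 for B and plasma cells. It was 0.491 and 0.555 for macrophages in the lower component, 0.538 and 0.382 for Kupffer cells and 0.57 and 0.496 for endothelial genes.

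Hepatocyte transcription factors fell with the index. Of the 13 listed factors 9 were measured, and HNF4A was not among them. Of these 9 members 6 fell and none rose, or 8 fell adjusted over the list alone. FOXA2, a pioneer factor of liver development, had a slope of -0.63 ± 0.071 (adjusted p = 1.3e-12) and FOXA3 of -0.41 ± 0.087 (adjusted p = 0.000105). ONECUT1 and NR0B2 had slopes of -0.094 ± 0.043 and -0.10 ± 0.062 (adjusted p = 0.113 and 0.261). ONECUT1 passed as lower among genes above the median mean (adjusted p = 0.0374). The score had r = -0.545 (-0.703 to -0.291) but rho = -0.308 (adjusted p = 0.00252), and r = -0.413 without the 2 farthest tumours. BIC favoured 2 components for this score (gain of 16.3), and Ashman's D was 3.87. Its lower component held 5 tumours, under the limit of 6, so only the size limit left r pooled. Camera gave an adjusted p of 7.02e-05, and an adjusted p of 0.0206 with an estimated correlation. With scores computed within each part the relation was -0.626 in the first 55 arrays and -0.271 in the last 55, where it no longer passed the threshold. It was -0.283 without the 5 farthest tumours, where the score relation kept its call and the camera call ended (adjusted p = 0.0672).

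Secreted hepatocyte proteins fell in 11 of 14 cases, or 12 adjusted over the list alone. Prothrombin, F2, had a slope of -0.42 ± 0.082 (adjusted p = 2.9e-05) and transferrin, TF, of -0.47 ± 0.10 (adjusted p = 7.49e-05), while haptoglobin, HP, had 0.17 ± 0.21 and FGB -0.10 ± 0.14 (adjusted p = 0.631 and 0.677). In the last 55 arrays the call of F2 ended, with a slope of -0.22 (adjusted p = 0.235). The camera call of 2.56e-05 was lost with an estimated correlation (adjusted p = 0.205). The score fell into separate clusters, with r = -0.562 in the lower 25 tumours (permutation p = 0.00324, adjusted p = 0.00723, rho = -0.577, r = -0.523 without 2, random lists -0.668 to 0.472) and r = -0.126 in the upper 85 (permutation p = 0.25, adjusted p = 0.329, rho = -0.0494, r = -0.0903 without 2). The upper component passed given component 1 (partial r = -0.368, adjusted p = 0.00108), a setting chosen after seeing the data. The lower component had r = -0.679 in the first 55 arrays and -0.106 in the last 55, where the call ended (adjusted p = 0.861). It also ended without the 5 farthest tumours, without the 5 least correlated arrays and with scores by median z (r = -0.445, -0.457 and -0.428, adjusted p = 0.0791, 0.0716 and 0.0669). Enzymes and transporters of hepatocyte metabolism fell in 4 of 20 cases, in either adjustment, and the other 16 did not pass. The urea cycle enzymes ARG1 and ASS1 had slopes of -0.59 ± 0.15 and -0.40 ± 0.11 (adjusted p = 0.0018 and 0.00371), and CYP1A2 and BAAT had 0.028 ± 0.19 and 0.028 ± 0.18 (adjusted p = 0.941 and 0.937). The metabolism score had r = -0.178 (-0.35 to 0.0279, permutation p = 0.0634, adjusted p = 0.115, rho = -0.0547, r = -0.0729 without 2 tumours), and its camera call of 0.0458 was lost with an estimated correlation (adjusted p = 0.693). In 2 settings chosen after seeing the data the metabolism score passed, centred within 10 blocks of the accession order (r = -0.344, adjusted p = 0.000625) and given component 1 (partial r = -0.271, adjusted p = 0.00739). Without the 5 farthest tumours it had r = -0.00546 (adjusted p = 0.966). Without the 5 farthest tumours ARG1, ASS1, TF and FOXA3 no longer passed (adjusted p = 0.295, 0.324, 0.336 and 0.0717), nor in the last 55 arrays (adjusted p = 0.611, 0.263, 0.423 and 0.213). ARG1 and ASS1 also lost their call without the 2 farthest tumours (adjusted p = 0.0575 and 0.083), with the index of transcription factors (0.0556 and 0.119) and with the 4 scores held (0.115 and 0.126).

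**Figure D2:**
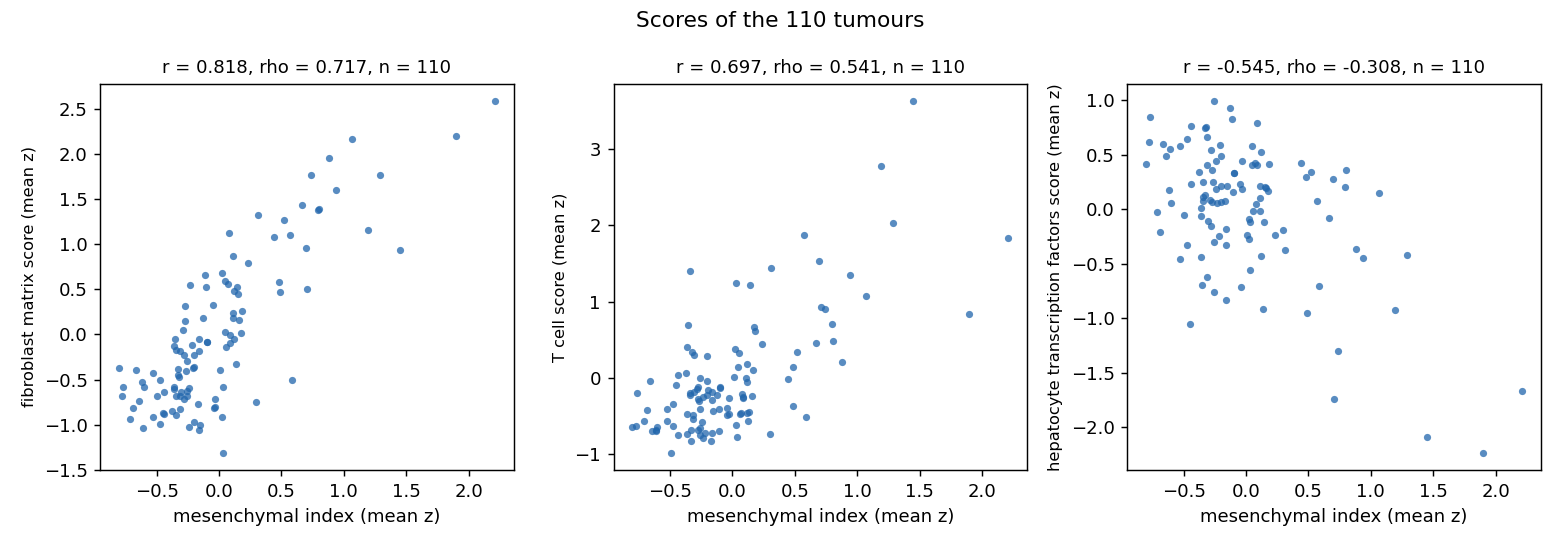
Scores of the fibroblast matrix, T cell and hepatocyte transcription factor lists against the mesenchymal index, all as mean z values, 1 point per tumour (n = 110). The first 2 scores climb with the index (r = 0.818 and 0.697), and the last goes down (r = -0.545).

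Of 12 epithelial junction and keratin genes 1 fell, in either adjustment, the keratin KRT8 at -0.25 ± 0.081 (adjusted p = 0.0146). Its call ended without the 2 and the 5 farthest tumours, without the 5 least correlated arrays, in the last 55 arrays, with blocks of the accession order and with the first component of reference genes in the model (adjusted p = 0.42, 0.564, 0.119, 0.457, 0.264 and 0.0671). OCLN, KRT18 and ESRP2 had slopes of -0.015 ± 0.0092, 0.024 ± 0.019 and 0.017 ± 0.0089 (adjusted p = 0.249, 0.41 and 0.169). KRT18 passed as higher without the 5 farthest tumours, at 0.054, and with the 4 stromal and leukocyte scores held, at 0.16 (adjusted p = 0.0403 and 0.00127). ESRP2 did so with those scores held, at 0.062 (adjusted p = 0.00591). The score had r = -0.148 (-0.395 to 0.177, permutation p = 0.123, adjusted p = 0.198, rho = 0.0699, r = 0.0605 without 2 tumours, camera adjusted p = 0.494). It passed in the first 55 arrays (r = -0.395, adjusted p = 0.00875) and centred within 10 blocks of the accession order (r = -0.222, adjusted p = 0.0368). It had r = 0.249 in the last 55 arrays (adjusted p = 0.122). Among 14 progenitor and oncofetal genes 1 rose and 1 fell, in either adjustment. Osteopontin, SPP1, rose by 0.85 ± 0.17 (adjusted p = 6.16e-05), and the imprinted gene PEG10 had a slope of -0.55 ± 0.17 (adjusted p = 0.00902), which with the mean of its probes was -0.22 (adjusted p = 0.0512). PEG10 did not pass in the first 55 arrays, without the 5 farthest tumours or with the 4 scores held either (adjusted p = 0.199, 0.0845 and 0.224). KRT19 and SALL4 had slopes of 0.15 ± 0.089 and -0.21 ± 0.085 (adjusted p = 0.256 and 0.0694). SALL4 passed as lower among genes above the median mean and with component 1 in the model (adjusted p = 0.0206 and 0.0311). The progenitor score had r = 0.292 in its lower 35 tumours (permutation p = 0.087, adjusted p = 0.148, rho = 0.409, adjusted p of rho = 0.0279, r = 0.223 without 2) and r = -0.109 in its upper 75 (permutation p = 0.35, adjusted p = 0.423, rho = -0.13, r = -0.0999 without 2), with a camera adjusted p of 0.951. None of 19 proliferation genes passed limma in either adjustment (3 at an unadjusted p under 0.05, camera adjusted p = 0.797). TYMS, RRM2, CENPF and FOXM1 had slopes of 0.14 ± 0.066, 0.051 ± 0.022, -0.12 ± 0.055 and -0.066 ± 0.036 (adjusted p = 0.116, 0.0982, 0.119 and 0.204). TYMS and RRM2 passed as higher without the 2 farthest tumours, without the 5 farthest and with the 4 stromal and leukocyte scores held (adjusted p = 0.0192, 0.0325 and 0.0194 for TYMS, 0.0344, 0.0313 and 0.000105 for RRM2). RRM2 did so by mean rank too (adjusted p = 0.0202). CENPF passed as lower with the index by median z, by mean rank and with component 1 in the model (adjusted p = 0.0481, 0.041 and 0.0276). FOXM1 did so with the index of transcription factors and with the first component of reference genes in the model (adjusted p = 0.0183 and 0.0376). The proliferation score had r = -0.147 in the lower 71 tumours (permutation p = 0.222, adjusted p = 0.307, rho = -0.162, r = -0.0664 without 2) and r = -0.0862 in the upper 39 (permutation p = 0.604, adjusted p = 0.673, rho = -0.0508, r = -0.00725 without 2).

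Of 15 beta-catenin targets in liver 3 fell, in either adjustment, with the hepatokine LECT2 at -0.57 ± 0.15 and the ubiquitin ligase RNF43 at -0.084 ± 0.028 (adjusted p = 0.00282 and 0.0226). The call of RNF43 ended in the first and last 55 arrays, without the 2 and the 5 farthest tumours, with blocks of the accession order, with both shorter indexes and with the 4 stromal and leukocyte scores held (adjusted p = 0.262, 0.175, 0.113, 0.293, 0.259, 0.234, 0.0665 and 0.405). That of LECT2 ended in the last 55 arrays, without the 5 farthest tumours and with the index of transcription factors (adjusted p = 0.241, 0.063 and 0.171). ODAM and APCDD1 had slopes of 0.022 ± 0.048 and 0.019 ± 0.02 (adjusted p = 0.792 and 0.559). Both passed as higher with the index of transcription factors (adjusted p = 0.0107 and 0.0281). The score had r = -0.137 (permutation p = 0.148, adjusted p = 0.226, rho = -0.134, r = -0.105 without 2 tumours), and camera an adjusted p of 0.207. Among 11 hypoxia and glycolysis genes 2 fell, or 1 adjusted over the list alone. BNIP3 had a slope of -0.39 ± 0.07 and VEGFA of -0.13 ± 0.048 (adjusted p = 4.25e-06 and 0.0487), and LDHA and SLC2A1 of 0.21 ± 0.09 and 0.16 ± 0.069 (adjusted p = 0.0883 and 0.0834). VEGFA lost its call in 9 alternatives without a treat limit, with adjusted p between 0.0818 and 0.431. BNIP3 did not pass in the last 55 arrays or with the index of transcription factors (adjusted p = 0.234 and 0.051). It turned to 0.11 with the 4 stromal and leukocyte scores held (adjusted p = 0.619). LDHA passed in 4 alternatives and SLC2A1 in 4. The hypoxia score had r = 0.00113 (permutation p = 0.991, adjusted p = 0.991, rho = 0.103, r = -0.0151 without 2 tumours, camera adjusted p = 0.969). None of 7 red blood cell genes passed limma in either adjustment (0 at an unadjusted p under 0.05), and HBB had a slope of 0.25 ± 0.15 (adjusted p = 0.237). Of these 7 genes 4 had a mean below 6.76, near background, so the lack of a call in the red blood cell list says little. The median slope of that list was -0.004 and its mean 0.031, so that median and mean differed in sign, and the direction of camera was lower (r = -0.0324, permutation p = 0.734, adjusted p = 0.788, rho = -0.118, r = 0.00802 without 2 tumours, camera adjusted p = 0.951). Of 8 housekeeping genes 2 rose, in either adjustment, YWHAZ by 0.44 ± 0.067 and ACTB by 0.28 ± 0.048 (adjusted p = 7.49e-08 and 2.12e-06), and the list had a camera adjusted p of 0.0655. The call of ACTB ended with the index of transcription factors (0.12, adjusted p = 0.147) and with the 4 stromal and leukocyte scores held (0.087, adjusted p = 0.582). The housekeeping score had r = -0.0974 in its lower 8 tumours (exact permutation p = 0.823, adjusted p = 0.852, rho = 0.143, r = 0.383 without 2) and r = 0.219 in its upper component, which held the other tumours (permutation p = 0.0263, adjusted p = 0.0509, rho = 0.276, adjusted p of rho = 0.0098, r = 0.271 without 2). The upper component passed in 8 alternatives, with r = 0.312 without the 5 farthest tumours (adjusted p = 0.00521). None of 12 genes of unrelated tissues, 8 of them with a mean below 6.76, passed limma in either adjustment (3 at an unadjusted p under 0.05, r = -0.0804, permutation p = 0.4, adjusted p = 0.464, rho = -0.0938, r = -0.0578 without 2 tumours, camera adjusted p = 0.887). Of these SYN1 passed as higher in 5 alternatives, with 0.081 without the 5 farthest tumours (adjusted p = 0.0237). MYOD1 passed as lower with the mean of its probes and with the 4 stromal and leukocyte scores held (-0.039 and -0.089, adjusted p = 0.0443 and 0.0255). CRYAA passed as lower with component 1 in the model (-0.33, adjusted p = 0.043).

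**Figure D3:**
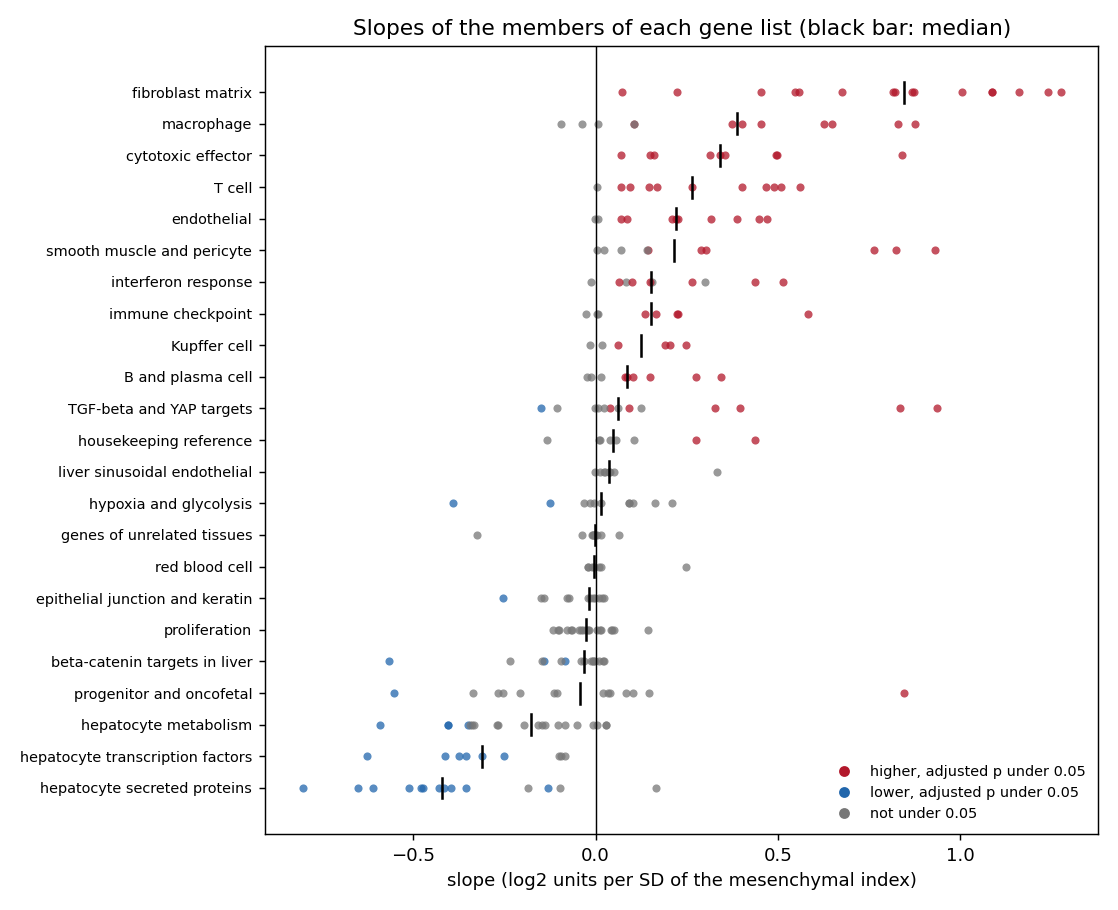
Slope of each measured member of the 23 gene lists in log2 units per SD of the mesenchymal index, 1 point per gene, with red for genes that rose, blue for genes that fell and grey for those that did not pass an adjusted p of 0.05 in limma. Black bars mark the medians, from -0.42 for hepatocyte secreted proteins to 0.85 for the fibroblast matrix.

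Across all 19921 genes outside the index, 2272 rose with it and 1911 fell (limma, adjusted p under 0.05), and 181 rose and 59 fell by at least 0.5 log2 units per SD. The genes named here had the strongest relations outside the lists and kept their sign in the first and the last 55 arrays. MYOF, a membrane repair protein, rose by 0.41 ± 0.021 (SE, adjusted p = 2.04e-34), the vesicle GTPase RAB31 by 0.70 ± 0.039 (adjusted p = 2.66e-30) and the carboxypeptidase inhibitor LXN by 0.58 ± 0.033 (adjusted p = 2.66e-30). The dermatan sulfate epimerase DSE rose by 0.54 ± 0.031, the heparan sulfatase SULF1 by 0.70 ± 0.041 and the hyaluronan receptor CD44 by 1.04 ± 0.067 (adjusted p = 5.11e-30, 2.02e-29 and 4.19e-26). The monocyte chemokine CCL2 rose by 0.85 ± 0.054, the formyl peptide receptor FPR3 by 0.51 ± 0.031, the adaptor FYB1 by 0.55 ± 0.035 and the oxysterol receptor GPR183 by 0.46 ± 0.03 (adjusted p = 1.23e-26, 2.32e-28, 4.76e-27 and 4.51e-25). KCTD12 rose by 0.58 ± 0.033 and the annexin ANXA1 by 0.80 ± 0.054 (adjusted p = 7.75e-30 and 1.87e-24).

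The strongest falls outside the lists were led by A1CF, the RNA-binding partner of the apolipoprotein B editing enzyme, with a slope of -0.65 ± 0.066 (adjusted p = 8.08e-15), and GJB1, the main gap junction protein of hepatocytes, with -0.65 ± 0.073 (adjusted p = 1.2e-12). The coagulation genes F7 and PROC had slopes of -0.76 ± 0.11 and -0.65 ± 0.088 (adjusted p = 2.53e-09 and 1.45e-09). The sterol-regulated membrane protein TMEM97 had -0.61 ± 0.072 and the nuclear receptor NR2F6 -0.39 ± 0.052 (adjusted p = 7.56e-12 and 8.38e-10). SH3BGRL2, HOOK1 and GAS2 had slopes of -0.49 ± 0.061, -0.46 ± 0.061 and -0.40 ± 0.054 (adjusted p = 9.01e-11, 9.7e-10 and 1.44e-09), and MTCH2 and CACFD1 of -0.26 ± 0.033 and -0.23 ± 0.032 (adjusted p = 1.25e-10 and 1.77e-09). The mitochondrial electron carrier subunit ETFB had -0.46 ± 0.063 (adjusted p = 2.17e-09), but its most variable probe had -0.029 (adjusted p = 0.904). Without the 5 tumours farthest from the median index, 1883 genes rose and 1558 fell; 0.507% and 0.0351% of the genes did so by at least 0.5, against 0.909% and 0.296% with all tumours. With 10 blocks of the accession order in the model, 2028 genes rose and 1307 fell. Of the 17110 probes without a gene name, 394 rose and 461 fell.

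Fibroblasts, leukocytes and endothelial cells express several index genes, so the relations of the other lists were computed again, in groups of at least 20 tumours, with the fibroblast matrix, T cell, macrophage and endothelial scores held. Of 22 partial relations 2 passed. The hepatocyte transcription factor score kept a partial r of -0.482 (permutation p = 1e-05, adjusted p = 0.00022), against -0.545 before. It was -0.533 (adjusted p = 0.00011) given the fibroblast score alone and -0.269 (adjusted p = 0.0282) given the T cell and macrophage scores alone. The housekeeping score had 0.312 (permutation p = 0.00163, adjusted p = 0.0179) in its upper component, against 0.219 without the scores held, which had not passed (adjusted p = 0.0509), and 0.243 (adjusted p = 0.0527) given the fibroblast score alone. The smooth muscle score had -0.0259 (permutation p = 0.79, adjusted p = 0.911), the TGF-beta and YAP score 0.0554 (permutation p = 0.573, adjusted p = 0.787), the cytotoxic score 0.111 (permutation p = 0.259, adjusted p = 0.57) and the checkpoint score 0.0766 (permutation p = 0.435, adjusted p = 0.728). Given the fibroblast score alone the cytotoxic, checkpoint and Kupffer cell scores passed, with 0.466 (adjusted p = 0.00011), 0.416 (adjusted p = 0.00022) and 0.311 (adjusted p = 0.00797). Given the T cell and macrophage scores alone the smooth muscle score passed with 0.493 (adjusted p = 0.00011) and the TGF-beta and YAP score with 0.426 (adjusted p = 0.00011). Hepatocyte metabolism had -0.166 (permutation p = 0.0892, adjusted p = 0.259), and hepatocyte secreted proteins had -0.275 (permutation p = 0.226, adjusted p = 0.554) in the lower 25 and -0.188 (permutation p = 0.0941, adjusted p = 0.259) in the upper 85 tumours. The epithelial score had -0.00639 (permutation p = 0.949, adjusted p = 0.949), the B and plasma cell score -0.0715 (permutation p = 0.463, adjusted p = 0.728), the Kupffer cell score -0.0948 (permutation p = 0.333, adjusted p = 0.665) and the sinusoidal score -0.187 (permutation p = 0.0554, adjusted p = 0.226). The other partial r lay between -0.251 and 0.32, with adjusted p of at least 0.0718. In the gene fit with the same 4 scores, 1815 genes rose and 1255 fell, of which 1548 were also called without them. There FCN3 turned to a slope of -0.86, ISG15 to -0.60, TAGLN to -0.51 and OAS2 to -0.40, all passing as lower (adjusted p = 0.0109, 0.0087, 0.00105 and 0.029). Members of the 4 held lists are not read from this fit, since holding the mean of a list pushes its members with a weak relation down by construction.

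Pairs of genes linked to epithelial-mesenchymal transition and to liver cancer subtypes were compared across tumours, with 33 relations from 21 pairs, of which 4 passed. VIM and the epithelial cadherin CDH1 had r = 0.274 (permutation p = 0.00367, adjusted p = 0.0303, rho = 0.312, r = 0.342 without 2 tumours), a positive relation that was 0.0633 in the first 55 arrays and lost its call there (adjusted p = 0.806). Its call also ended with the mean of probes (r = 0.224, adjusted p = 0.0868) and without the 5 least correlated arrays (r = 0.259, adjusted p = 0.0551). ZEB1 and VIM had r = 0.326 (permutation p = 0.00061, adjusted p = 0.00726, rho = 0.335, r = 0.303 without 2 tumours), and r = 0.277 in the first 55 arrays, where the call ended. CD8A and VIM had r = 0.5 (permutation p = 1e-05, adjusted p = 0.00033, rho = 0.522, r = 0.537 without 2 tumours). EPCAM fell into separate clusters, and within its upper 64 tumours EPCAM and KRT19 had r = 0.413 (permutation p = 0.00066, adjusted p = 0.00726, rho = 0.502, r = 0.405 without 2 tumours), with a call that ended in the first 55 arrays (r = 0.332), while in the lower 46 they had r = -0.0325 (permutation p = 0.833, adjusted p = 0.87, rho = -0.144, r = 6.93e-05 without 2 tumours). The relation of ZEB1 with its known target CDH1 did not pass, with r = 0.237 (permutation p = 0.0124, adjusted p = 0.0818, rho = 0.208, r = 0.212 without 2 tumours), nor did that of SNAI2 with CDH1, with r = -0.0862 (permutation p = 0.372, adjusted p = 0.571, rho = 0.0984, r = 0.0777 without 2 tumours). TGFB1 and VIM had r = 0.0216 (permutation p = 0.823, adjusted p = 0.87, rho = 0.0814, r = 0.0721 without 2 tumours). The mean level of TGFB1 was 6.54 with an SD of 0.083, near background, so this r cannot show that they are unrelated. The same holds for ZEB1 and CDH1, since ZEB1 had a mean of 6.51 with an SD of 0.101. AFP and VIM had r = -0.222 (permutation p = 0.0643, adjusted p = 0.212, rho = -0.21, r = -0.289 without 2 tumours) in the lower 70 tumours of AFP and r = 0.373 (permutation p = 0.0184, adjusted p = 0.101, rho = 0.363, r = 0.305 without 2 tumours) in the upper 40. VIM and CDH2 had r = -0.196 (permutation p = 0.049, adjusted p = 0.199, rho = -0.222, r = -0.16 without 2 tumours) in the upper component of CDH2, which held all but 9 tumours. The other relations did not pass with all tumours and the brightest probes, among them ZEB1 and ESRP1 in the upper 6 tumours of ESRP1, with r = -0.855 (exact permutation p = 0.0542, adjusted p = 0.199, rho = -0.486, r = 0.897 without 2 tumours). FN1 and ALB had r = -0.0307 (permutation p = 0.75, adjusted p = 0.87, rho = -0.121, r = -0.0381 without 2 tumours), but with the most variable probe of each gene r = 0.326 (adjusted p = 0.00545). The brightest probe of FN1 had a mean of 6.89 with an SD of 0.142, near background. ALB had a mean of 14.4, close to the highest value of 15. The r with the brightest probes thus cannot show that FN1 and ALB are unrelated. With the most variable probes FN1 and VIM passed too (r = 0.276, adjusted p = 0.0203). ZEB2 and CDH1 passed in the last 55 arrays within the lower component of ZEB2 (r = 0.369, adjusted p = 0.0337).

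The 15 genes that varied most between tumours were named by their SD. The alcohol- and drug-metabolising enzyme CYP2E1 had an SD of 2.95 log2 units around a mean of 10.83, the trypsin inhibitor SPINK1 an SD of 2.84, the imprinted RNA H19 2.71, the acute-phase protein CRP 2.59 and alpha-fetoprotein, AFP, 2.54. AKR1B10, HRG, IGLL1, DLK1, CYP2C8, REG3A, CPS1, SERPINC1, ADH1C and HPD followed with SDs between 2.23 and 2.53, against a median SD of 0.25 over all genes. Of these 15 genes 2 changed with the index. IGLL1, an immunoglobulin light chain-like gene, rose by 1.39 ± 0.20 (adjusted p = 9.32e-09) and CRP by 0.71 ± 0.24 (adjusted p = 0.0227). The call of CRP ended in the first and last 55 arrays, with the index of transcription factors, with the index without leukocyte-expressed genes, with the first component of reference genes in the model and with the 4 stromal and leukocyte scores held. The adjusted p of CRP there were 0.303, 0.0637, 0.435, 0.121, 0.0932 and 0.793. IGLL1 turned to -0.56 with the 4 scores held (adjusted p = 0.198). CYP2E1 had a slope of -0.10 ± 0.28 and AFP of -0.34 ± 0.24 (adjusted p = 0.85 and 0.352).

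The first principal component of the 5000 most variable genes held 24.3% of their variance and component 2 held 11.9%. Component 1 did not follow the index, with r = 0.0114 (rho = 0.137, r = -0.000775 without 2 tumours, adjusted p = 0.922), but went with hepatocyte genes. It had r = 0.727 (rho = 0.726, r = 0.722 without 2 tumours, adjusted p = 5.45e-05) for hepatocyte metabolism, r = 0.508 (rho = 0.443, r = 0.487 without 2 tumours, adjusted p = 5.45e-05) for hepatocyte transcription factors and r = 0.696 (rho = 0.698, r = 0.686 without 2 tumours, adjusted p = 5.45e-05) for secreted proteins in their upper 85 tumours. It also followed the housekeeping score in its upper component, with r = 0.408 (rho = 0.37, r = 0.417 without 2 tumours, adjusted p = 0.000185), and the endothelial score, with r = 0.482 (rho = 0.547, r = 0.439 without 2 tumours, adjusted p = 5.45e-05). Component 2 followed the index, with r = 0.64 (rho = 0.586, r = 0.623 without 2 tumours, adjusted p = 5.45e-05). It had r = -0.558 (rho = -0.566, r = -0.565 without 2 tumours, adjusted p = 5.45e-05) for hepatocyte metabolism, r = 0.417 (rho = 0.321, r = 0.378 without 2 tumours, adjusted p = 0.0001) for immune checkpoints and r = 0.482 (rho = 0.421, r = 0.46 without 2 tumours, adjusted p = 5.45e-05) for the fibroblast matrix. The housekeeping score in its upper component had r = 0.496 with component 2 (rho = 0.453, r = 0.462 without 2 tumours, adjusted p = 5.45e-05). Genes of unrelated tissues had r = -0.293 (rho = -0.249, r = -0.167 without 2 tumours, adjusted p = 0.00653). Component 2 was thus not particular to stromal, immune and hepatocyte genes. Component 3, with 6.87% of the variance, followed the index too, with r = 0.652 (0.474 to 0.765, permutation p = 1e-05, rho = 0.542, r = 0.565 without 2 tumours), in a test added after the data were seen. Components 1 and 2 were set against the lists in 60 relations, and the permutation p behind the adjusted value of 5.45e-05 is again the smallest that the permutations can give.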

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

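The settings without the 5 farthest tumours, with accession blocks and given component 1 were chosen after seeing the data, as was the gene fit without the 2 farthest tumours; the rest were planned. Of 14 called list relations, 10 stayed called with their sign in the alternatives run. Their r ranged over 0.603 to 0.847 for the fibroblast matrix, 0.522 to 0.745 for smooth muscle, 0.474 to 0.799 for TGF-beta and YAP targets, 0.458 to 0.799 for T cells and 0.408 to 0.75 for cytotoxic genes. It ranged over 0.27 to 0.478 for B and plasma cells, 0.26 to 0.716 for macrophages in the lower component, 0.277 to 0.672 for Kupffer cells, 0.447 to 0.608 for endothelial genes and 0.353 to 0.661 for checkpoints. Hepatocyte transcription factors ranged over -0.64 to -0.271. Of 131 named genes, 129 kept direction and side of the threshold with the most variable probe, a rule that reads only 7 of them from another probe, 99 without the 5 farthest tumours and 76 with the 4 scores held. The principal components kept theirs in the 3 alternatives run. Further quantile normalization and median centring moved nothing, since the distributions of the arrays were already equal, and say nothing about stability. The alternative for linear intensities was not run, since the values are on a log2 scale. Signal over background limits the dim genes, with 6 of 18 index genes below the median of probe means. The smaller number of arrays in each part of the series and the stricter treat limit lower the number of called genes by construction. For the other changes below, sizes in the first 55 arrays included, the cause was not tested. Percentages are of the 19921 genes, of which 0.909% rose and 0.296% fell by 0.5 or more with all tumours. Components of a split score are given as (lower) and (upper). Outside the treat limit and the fit with 4 scores held, the call of a named gene ended in at least 1 alternative for ACTB, AJUBA, ARG1, ASS1, BNIP3, CRP, ETFB, F2, FOXA3, KRT8, LCK, LECT2, OAS2, PEG10, RNF43, TF and VEGFA, and AMOTL2, APCDD1, CENPF, CRYAA, FCGR3A, FCN3, FOXM1, KRT18, LAIR1, LDHA, LYVE1, MYOD1, ODAM, ONECUT1, RRM2, SALL4, SDHA, SERPINC1, SLC2A1, SYN1, TRAT1 and TYMS gained a call in at least 1.

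With genes above the median mean, r passed at 0.373 for progenitor (lower) and 0.236 for housekeeping (upper), r no longer passed at 0.811 for macrophage (upper), and r turned sign, not passing, to -0.00628 for hypoxia, 0.0769 for red blood cell and 0.54 for housekeeping (lower). With the mean of probes, r passed at 0.236 for housekeeping (upper), and r turned sign, not passing, to 0.244 for housekeeping (lower). With the most variable probe, r turned sign, not passing, to 0.0113 for housekeeping (lower), and r turned to 0.326 for FN1 and ALB. Without the 5 least correlated arrays, r passed at 0.249 for housekeeping (upper), r no longer passed at -0.457 for secreted proteins (lower), r turned sign, not passing, to -0.0391 for hypoxia and 0.0233 for red blood cell, and 0.186% of genes fell by 0.5 or more. In the first 55 arrays, r passed at -0.395 for epithelial, r no longer passed at 0.294 for interferon response (lower), r turned sign, not passing, to 0.0359 for proliferation (upper), -0.0486 for hypoxia and 0.0867 for unrelated tissues, and 825 genes fell, 1.37% of genes rose by 0.5 or more and 0.612% of genes fell by 0.5 or more. In the last 55 arrays, r passed at 0.365 for housekeeping (upper), r no longer passed at -0.106 for secreted proteins (lower) and -0.271 for transcription factors, r turned sign, not passing, to 0.0994 for secreted proteins (upper), 0.0272 for hepatocyte metabolism, 0.249 for epithelial and -0.00628 for hypoxia, and 1305 genes rose, 649 genes fell and 0.0351% of genes fell by 0.5 or more. Scored by their first component, r passed at 0.242 for housekeeping (upper), and r turned sign, not passing, to 0.0438 for red blood cell, 0.251 for housekeeping (lower) and 0.111 for unrelated tissues. Scored by median z, r no longer passed at -0.428 for secreted proteins (lower) and 0.724 for macrophage (upper), r turned sign, not passing, to 0.00468 for progenitor (upper), -0.116 for interferon response (upper) and 0.154 for housekeeping (lower), and 0.161% of genes fell by 0.5 or more. Scored by mean rank, r passed at 0.228 for hypoxia, and 0.166% of genes fell by 0.5 or more. With an index of transcription factors, r no longer passed at 0.919 for macrophage (upper) and 0.105 for interferon response (lower), r turned sign, not passing, to 0.00694 for hepatocyte metabolism, 0.126 for beta-catenin, -0.16 for hypoxia and 0.0285 for red blood cell, and 0.296% of genes rose by 0.5 or more and 0.0351% of genes fell by 0.5 or more. With the index without leukocyte genes, r no longer passed at 0.207 for interferon response (lower), r turned sign, not passing, to -0.00212 for hypoxia, and 1044 genes fell, 0.542% of genes rose by 0.5 or more and 0.161% of genes fell by 0.5 or more. Without the 2 farthest tumours, r passed at 0.271 for housekeeping (upper), r turned sign, not passing, to 0.0605 for epithelial, -0.0151 for hypoxia and 0.00802 for red blood cell, and 0.0853% of genes fell by 0.5 or more. Without the 5 farthest tumours, r passed at 0.312 for housekeeping (upper), r no longer passed at -0.445 for secreted proteins (lower) and 0.21 for interferon response (lower), r turned sign, not passing, to 0.159 for epithelial, -0.0342 for hypoxia and 0.0279 for red blood cell, partial r turned sign, not passing, to 0.114 for epithelial, 0.236 for progenitor (lower), -0.00654 for proliferation (lower), 0.0307 for beta-catenin, 0.0105 for Kupffer cell and 0.00323 for red blood cell, 0.507% of genes rose by 0.5 or more and 0.0351% of genes fell by 0.5 or more, and camera called 0 lists lower, against 3, and 13 higher, against 11, with sinusoidal endothelium and housekeeping gained (adjusted p = 0.0125 and 0.00634). With the 4 stromal and leukocyte scores held, slopes turned sign to -0.34 for PDGFRB, -0.51 for TAGLN, -0.13 for LTBP2, -0.029 for LCK, -0.014 for CD79A, -0.033 for ENG, -0.86 for FCN3, -0.40 for OAS2, -0.60 for ISG15, 0.11 for BNIP3 and -0.56 for IGLL1 (PDGFRB, LCK and ENG belong to held lists, whose own mean lowers them by construction), with FCN3, ISG15, TAGLN and OAS2 passing as lower, outside held lists the calls of ACTB, AJUBA, ARG1, ASS1, CRP, FOLR2, GNLY, GZMA, GZMK, HAVCR2, IDO1, IFI44L, KLRD1, PEG10, RNF43, TNFRSF17, VEGFA and VSIG4 ended and those of ESRP2, KRT18, MYOD1, RRM2, SLC2A1 and TYMS were gained, and 1255 genes fell and 1.14% of genes fell by 0.5 or more. With a treat limit of 0.2, 353 genes rose, 56 genes fell and 0.166% of genes fell by 0.5 or more. With 10 accession blocks in the model, 0.507% of genes fell by 0.5 or more. Centred within the 10 blocks, r passed at -0.344 for hepatocyte metabolism and -0.222 for epithelial, and r turned sign, not passing, to -0.0131 for hypoxia. Given component 1, r passed at -0.368 for secreted proteins (upper), -0.271 for hepatocyte metabolism and 0.284 for housekeeping (upper). With an estimated correlation, camera called 1 list lower, against 3, and 9 higher, against 11. With the fibroblast score alone held, partial r passed at 0.466 for cytotoxic effector and 0.416 for immune checkpoint, partial r no longer passed at 0.243 for housekeeping (upper), partial r turned sign, not passing, to 0.0853 for progenitor (lower), -0.0956 for proliferation (lower), 0.0146 for beta-catenin, 0.197 for B and plasma cell, 0.105 for interferon response (lower) and 0.00908 for red blood cell, and partial r turned sign and passed at 0.311 for Kupffer cell. With the T cell and macrophage scores alone held, partial r passed at 0.426 for TGF-beta and YAP targets, partial r turned sign, not passing, to 0.0999 for epithelial, -0.0793 for cytotoxic effector, -0.136 for immune checkpoint and -0.0783 for hypoxia, and partial r turned sign and passed at 0.493 for smooth muscle.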

Other observations

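The relations among lists in the next paragraphs and the genes related to the beta-catenin score were added after the data were seen, and the tests of dilution, of an equal fall, of the 5 farthest tumours, of component 1, of the parts of the series, of leukocyte genes in the index, of accession order, of array quality and of shuffled orders were chosen after the results they bear on were seen. Scores of hepatocyte metabolism went down where progenitor and oncofetal genes were high. The relation had r = -0.5 (permutation p = 0.00228, adjusted p = 0.00646, rho = -0.581, r = -0.47 without 2 tumours) in the lower 35 tumours of the progenitor score and r = -0.532 (permutation p = 1e-05, adjusted p = 0.00017, rho = -0.533, r = -0.507 without 2 tumours) in the upper 75. Sinusoidal endothelial markers followed hepatocyte metabolism, with r = 0.331 (permutation p = 0.00028, adjusted p = 0.000952, rho = 0.315, r = 0.336 without 2 tumours), and the general endothelial score, with r = 0.355 (permutation p = 0.00013, adjusted p = 0.000637, rho = 0.451, r = 0.372 without 2 tumours). Targets of beta-catenin followed hepatocyte metabolism as well, with r = 0.354 (permutation p = 0.00015, adjusted p = 0.000637, rho = 0.255, r = 0.319 without 2 tumours) and with r of 0.255 and 0.383 in the first and last 55 arrays. The beta-catenin score had r = -0.0622 (permutation p = 0.529, adjusted p = 0.643, rho = -0.0798, r = -0.0654 without 2 tumours) with the macrophage score in its lower component, and in its upper 6 tumours r = -0.819 (exact permutation p = 0.0181, adjusted p = 0.0438, rho = -0.886, r = -0.886 without 2 tumours), where rho did not pass (adjusted p = 0.0708). These belong to 17 relations. Component 1, which varied along the accession order, followed the metabolism score, so all but the relation in those 6 tumours were computed again, after the data were seen, centred within 10 blocks of the accession order and given component 1. With metabolism, r was -0.504 and -0.498 for the lower and -0.545 and -0.438 for the upper progenitor component, 0.298 and 0.255 for the sinusoidal and 0.366 and 0.419 for the beta-catenin score, and all passed. Sinusoidal with endothelial markers had 0.328 and 0.291, passing as well.

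A fit on the beta-catenin score called 436 genes higher and 155 lower (limma), 34 and 9 of them by at least 0.5 log2 units per SD. The transcriptional regulator ZNF503 rose by 0.64 ± 0.046 (SE, adjusted p = 1.78e-21), the adhesion protein HEPACAM by 0.91 ± 0.077 (adjusted p = 1.66e-17), the claudin CLDN2 by 0.65 ± 0.058 (adjusted p = 3.42e-16) and the organic anion transporter SLC22A11 by 0.66 ± 0.059 (adjusted p = 3.42e-16). The growth factor VEGFB had a slope of -0.54 ± 0.09 (adjusted p = 7.56e-06), the desmosomal cadherin DSG2 of -0.52 ± 0.093 (adjusted p = 3.66e-05) and histidase, HAL, of -0.54 ± 0.11 (adjusted p = 0.000278). In the hepatocyte metabolism list 8 of 20 genes rose, or 10 adjusted over the list alone, and the camera call was lost (adjusted p = 0.134 with an estimated correlation). Without the 5 tumours farthest from the median score 141 genes rose and 27 fell, 12 and 1 of them by at least 0.5. Of 100 shuffled scores 1 called as many genes, with a highest count of 654 above the count in the real order.

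A loss of hepatocyte enzymes with proliferation was tested as a hypothesis, chosen after the component of 71 tumours was known and before this relation was computed. In the 71 tumours of the lower proliferation component the score of hepatocyte metabolism had r = -0.438 (permutation p = 0.00015, adjusted p = 0.000637, rho = -0.44, r = -0.481 without 2 tumours), with an interval of -0.651 to -0.182 and r of -0.231 and -0.544 in the first and last 55 arrays. In the upper 39 it had r = -0.283 (permutation p = 0.0799, adjusted p = 0.151, rho = -0.325, r = -0.303 without 2 tumours). Centred within blocks and given component 1, r was -0.335 and -0.432 in the lower component, passing in both, and -0.112 and -0.363 in the upper, passing in neither. Hepatocyte transcription factors had r = 0.0989 (permutation p = 0.414, adjusted p = 0.587, rho = 0.0963, r = -0.0138 without 2 tumours) in the lower 71. Fewer T cells where beta-catenin targets are high was a further hypothesis chosen before its relation was computed. The beta-catenin and T cell scores had r = -0.091 (permutation p = 0.34, adjusted p = 0.526, rho = 0.0235, r = -0.0818 without 2 tumours), with an interval of -0.227 to 0.0746, which leaves a weak negative relation open.

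Hepatocyte transcription factors fell with the index, and no biological explanation was tested, since the labels name 1 group. Dilution of hepatocytes by fibroblasts and leukocytes stays open. The partial r was -0.482 given the 4 scores that stand for those cells (-0.612 to -0.312), and -0.533 to -0.269 with fewer scores held. The scores as measured thus do not carry the whole relation, but dilution that they miss would leave a negative partial r too. The housekeeping score also passed in that test, in its upper component (partial r = 0.312, adjusted permutation p = 0.0179). The 5 tumours with the most extreme index as the whole cause are argued against by r = -0.283 without them. Tumours with an outlying score were not left out as such. A tumour with a score of -1.75 and an index of 0.707 stayed in. A few tumours with low scores as the source were therefore not tested. Array quality along component 1 would need an r of component 1 with the index of 0.545 in size to carry the whole relation. That r was 0.0114 (-0.182 to 0.224), but it was known before the test was chosen, so the outcome was fixed. Quality along component 2 was not tested, though it followed the index (r = 0.64) and the housekeeping score in its upper component (r = 0.496). On other axes, r was -0.532 without the 5 least correlated arrays. FOXA2 and FOXA3 kept slopes of -0.57 and -0.47 with the first component of reference and unrelated genes in the model. An equal fall of all hepatocyte genes stays open, since the mean slope of the transcription factors minus that of the metabolism genes was -0.084 (-0.23 to 0.057). The relation may differ along the series, with r = -0.672 and -0.212 in the first and last 55 arrays for scores computed over all tumours, and a permutation p of 0.0328 for the difference, not corrected over lists, over 10000 random splits.

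The T cell score rose with the index, and no biological explanation was tested. Leukocyte transcripts in the index stay open, since the relation had r = 0.58 without 6 index genes that leukocytes are known to express, but ZEB1, AXL and MMP14 among the other 12 are known from T cells or macrophages too. Array quality along component 1 as the whole cause is argued against by the same r of 0.0114, since 0.697 would be needed; on other axes, r was 0.705 without the 5 least correlated arrays, and CD6 and IL7R kept slopes of 0.41 and 0.56 with the first component of reference and unrelated genes in the model. Whether the index is read from tumour cells or from stromal cells that come with T cells stays open.

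Component 1 followed hepatocyte genes and not the index, and no biological explanation was tested. Neighbouring arrays in the accession order had like values of component 1, with a correlation of 0.501 (permutation p = 1e-05, the smallest that the permutations can give), against 0.122 for the index (permutation p = 0.0833). Processing or submission order is thus a candidate source of part of component 1, though tumours of like kind may also have been submitted together. Array or RNA quality cannot be told apart from biology here, since component 1 had r = 0.755 with the median correlation of each array with the others (rho = 0.651, r = 0.728 without 2 tumours), which a strong biological axis would give too. The dimmest genes had a median r of -0.0664 with component 1, short of the 0.3 that the test asked for, and within the 0.1 of 0 that an earlier form of the test, replaced after its value was seen, took as evidence against quality, but genes near background exclude nothing.

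A random order of the tumours as the source of the count of genes related to the index is argued against by shuffled orders. The real order of tumours called 4183 genes, only 1 order (the real one) gave as many, and the highest of 100 shuffled orders gave 239. No index of random genes was run, and genes on the same arrays vary together. The count is therefore not shown to be particular to mesenchymal genes.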
